A study of Mus musculus with 7 samples.

How the data were processed

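RNA from 7 cultures was measured, 3 transduced with retroviruses for MYC, BMI1 and BCLXL and 4 transduced with these and IRF4. Per the labels, mouse spleen cells were stimulated with 25 µg/ml lipopolysaccharide, transduced on days 2 and 3, and kept in culture for 6 to 12 weeks; the time of each culture was not given in the sources used here. The labels call the cultures biological replicates. Total RNA was extracted with Trizol, prepared with the Ambion WT Expression kit and labelled with the Affymetrix WT Terminal Labeling kit, per the labels' protocols. The submitters' processing notes name Affymetrix Expression Console. Its version, the background correction and the normalization are not given in the sources used here. The labels do not say from which species the transduced cDNAs were taken, nor which parts of the transcripts they hold.

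The deposited values are intensities on a linear scale, between 3.18 and 8659.09, for 35556 probe sets on each array. All of them (100%) equalled 2 to a power with 2 decimals within 0.005, so the authors' values had been on the log2 scale and were put back on it here. Array medians lay between 3.89 and 4.05 and upper quartiles between 7.26 and 7.33 (log2), so the arrays had been brought to one scale before deposit. Intensities carry no counts and no detection calls. A difference against a dim group therefore has no formal bound, and its size depends on the signal floor. The array's probe annotation gave 1 gene symbol for 21218 probe sets, several for 1881 and none for 12457. Of the first, 21185 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, and the match changed 0 symbols. No gene was named from a probe set with several symbols, and no coordinates were used.

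A gene was the probe set with 1 symbol of highest mean log2 intensity, which gave 18820 genes, 1386 of them with more than 1 probe set. Genes were kept where at least 3 arrays lay above the array's 40th percentile over all probe sets, which left 11723 for testing. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the tested genes), with adjusted p under 0.05 as threshold and a log2 difference of at least 1 for a 2-fold call. The design held the group alone. On data simulated from the means and spreads of these 11723 genes for this comparison, with 200 genes changed, the fit recovered 64% of genes changed 2-fold and 92% of those changed 4-fold. Of its calls, 8.77% fell on unchanged genes, above the 0.05 of the threshold. The simulated genes varied independently, and far fewer of them were changed than the 36.5% of tested genes called in the real data. These rates may therefore not hold for the real comparison.

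Before the data were examined, 33 gene lists, the alternatives and the rule for named genes were fixed. The lists covered plasma cell genes, mature B cell genes, B cell progenitors, germinal centre cells, B-1 and marginal zone cells, class I and class II presentation, receptor signalling, secretory pathway, ATF4 targets, NF-kappaB targets, interferon-stimulated genes, proliferation, MYC targets, cyclins and their inhibitors, the BCL2 family, p53 targets, Polycomb and Hox genes, myeloma genes, adhesion, glycolysis, oxidative phosphorylation, sterol synthesis, autophagy, ribosomal proteins, immunoglobulin constant regions, the transduced genes and markers of 6 other lineages. Of 857 entries, 762 matched a probe set with 1 symbol. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. Camera asks whether a list moved relative to other genes. Fry's directional test asks whether a list's genes move, on balance, one way, and its mixed test whether they change in either direction; neither compares the list with other genes.

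The text names the 4 transduced genes and a set of fixed markers, some of which are not reported here, the 8 largest differences in each direction among called genes whose groups do not overlap, up to 4 members of a list by size of difference, and constant region and variable segments picked out by the immunoglobulin rule. Immunoglobulin and T cell receptor segments, predicted genes and small RNA genes were left out of the largest differences. Slamf7 and Tbx21, and in the closing section Ptprc, Spi1, Pou2af1, Laptm5, Lcp1 and Xist, were named after their values were seen. For immunoglobulin genes, each array was set against the median of the other arrays and probe sets at least 8-fold above it were listed, with no test. Alternatives were no filter, a filter at the 60th percentile, quantile normalization, equal array medians, the mean of a gene's probe sets, array weights, eBayes with trend and robust settings, the replicate number as a block, each array left out in turn, each probe set on its own, limma's treat against 0.58, and for lists an estimated correlation, fry and members in no other list. The labels give no array batch, scan day or culture batch, so none was tested.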

Results

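Gene expression was measured in 7 cultures of transformed mouse B cells with whole-transcript Affymetrix arrays. Spleen cells of C57BL/6 mice had been stimulated with lipopolysaccharide, a bacterial product that activates B cells, and transduced with retroviruses. In 3 cultures the retroviral pool encoded MYC, BMI1 and BCLXL, and in 4 cultures it also encoded IRF4, a transcription factor needed for plasma cell formation. The submitters described the first group as resembling mature B cells or lymphoma cells and the second as resembling plasma cells or myeloma cells. Each culture came from its own spleen preparation and its own virus preparation. The question was how the cells grown out with IRF4 in the pool differed from those grown out without it. Groups are named here as labelled, because the array did not show IRF4 itself where the labels place it. Values are log2 intensities, given as mean ± SD with n = 3 arrays labelled without IRF4 and n = 4 labelled IRF4. Differences are the arrays labelled IRF4 minus those labelled without IRF4, with their standard error (SE). The number of arrays limits the precision, and no array carried a detection call.

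The mouse Irf4 probe set (10404389) was lower, not higher, on the arrays labelled IRF4. Its log2 intensity was 8.76, 8.67 and 8.73 on the 3 arrays labelled without IRF4. It was 3.79, 4.47, 4.67 and 4.69 on the 4 arrays labelled IRF4, which is a fall of 19.9-fold (difference -4.32 ± 0.22 SE, adjusted p = 2.99e-05). The direction therefore went against the label. The other transduced genes lay at or under 5.69 on every array. Myc (10424400) lay at 3.22 ± 0.02 and 3.29 ± 0.12, below the filter for testing. Bmi1 (10469514), a Polycomb protein gene, lay at 3.39 ± 0.23 and 3.72 ± 0.46 (adjusted p = 0.354). Bcl2l1 (10488655), which encodes the survival protein BCL-XL, lay at 4.76 ± 0.19 and 5.27 ± 0.29 (adjusted p = 0.0652), and passed at adjusted p = 0.0424 when array medians were set equal (0.0424 to 0.204 over all settings). The median of all probe sets lay between 3.89 and 4.05 on the 7 arrays, so Myc lay under the median of every array and Bcl2l1 above it. Of the 3 transduced genes tested, none rose, 1 fell and 2 did not pass, while adjusted over the list alone Bcl2l1 passed as higher and Irf4 as lower.

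**Figure D1:**
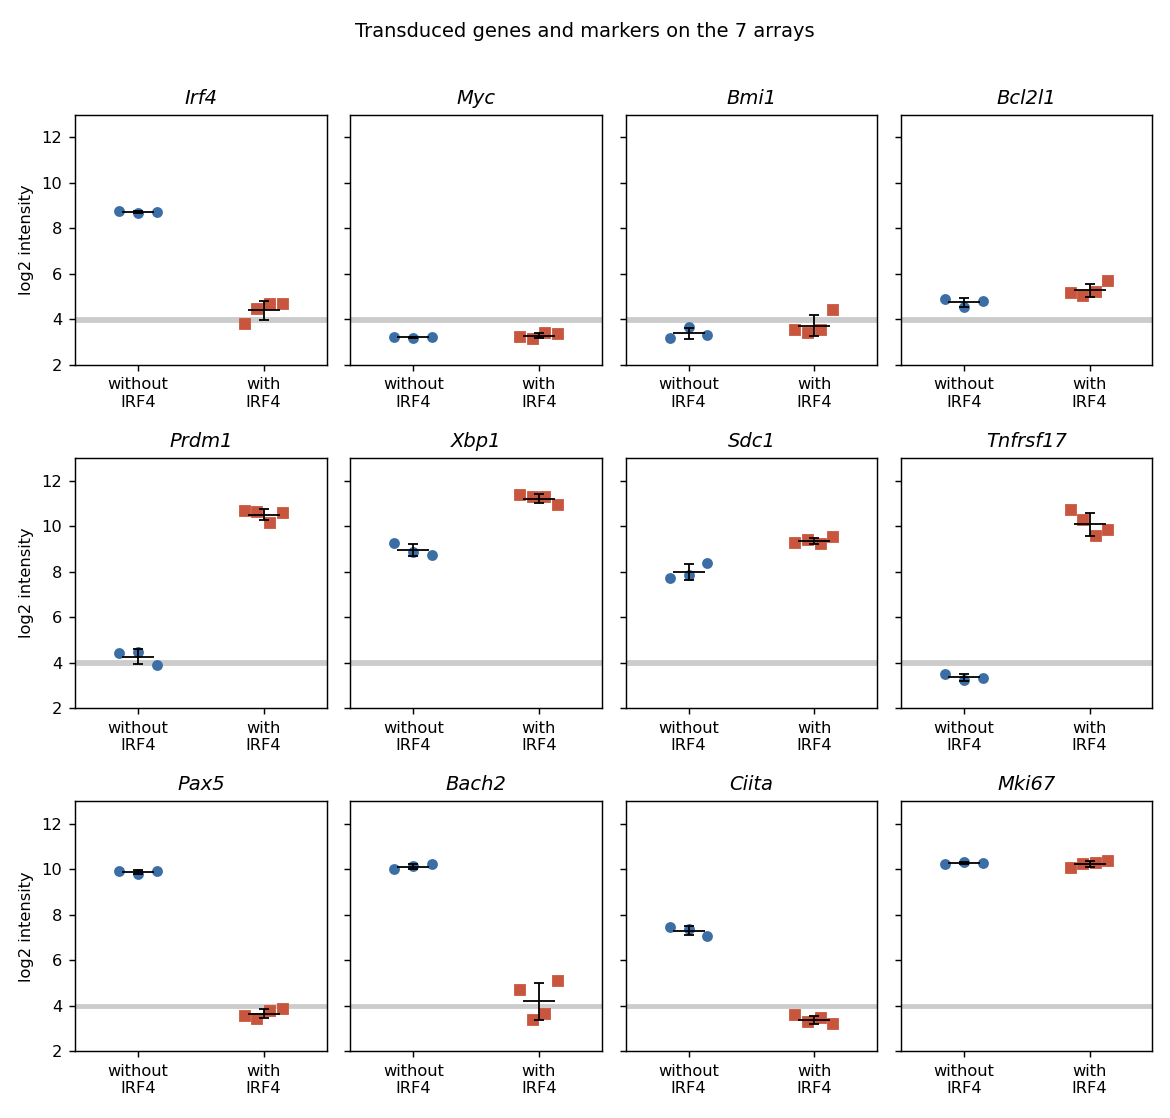
Log2 intensity of the 4 transduced genes and of 8 marker genes, with 1 point per array (circles, labelled without IRF4; squares, labelled IRF4), a bar for the mean with its SD, and a grey band over the range of the array medians. The mean of Irf4 fell from 8.72 to 4.40, Prdm1, Xbp1, Sdc1 and Tnfrsf17 were higher on the arrays labelled IRF4, and Mki67 lay between 10.06 and 10.35 on all 7.

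More genes of plasma cells rose than fell on the arrays labelled IRF4. Prdm1, which encodes the plasma cell regulator BLIMP-1, rose 75.6-fold, from 4.27 ± 0.31 to 10.51 ± 0.24 (difference 6.24 ± 0.19 SE, adjusted p = 3.26e-06). Tnfrsf17, the gene of the survival receptor BCMA, rose from 3.36 ± 0.15 to 10.08 ± 0.51 (adjusted p = 1.09e-05). Xbp1, a regulator of the secretory programme, rose by 2.26 ± 0.16 SE (adjusted p = 0.000138), and Sdc1, the gene of the surface protein CD138, by 1.35 ± 0.18 SE (adjusted p = 0.00167). In the list of plasma cell genes, 16 of the 27 tested members rose, 6 fell and 5 did not pass. Adjusted over the list alone, 16 rose and 7 fell. The members that fell included Cd93 (-5.59 ± 0.30 SE), the secretory chaperone gene Mzb1 (-5.21 ± 1.01 SE) and the surface receptor gene Slamf7 (-3.61 ± 0.44 SE, named after its value was seen). Mzb1 was uneven, at 8.14 on replicate 3 labelled IRF4 against 3.99 to 4.96 on the other 3. Jchain, the joining chain gene of secreted IgM and IgA, lay at 2.93 ± 0.06 and 3.05 ± 0.15, below the filter. The median difference of the list was 2.05 (1.12 with no filter), and the camera test called it higher (adjusted p = 0.000332), a call that was lost at adjusted p = 0.212 with an estimated correlation.

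Genes of mature B cells fell almost throughout. Pax5 and Ebf1, transcription factors that hold B cell identity, had log2 differences of -6.22 ± 0.12 SE and -6.85 ± 0.13 SE (adjusted p = 8.3e-07 for both). Bach2, a repressor of Prdm1 in B cells, had a difference of -5.93 ± 0.42 SE, and Cd79b, a signalling chain of the B cell receptor, one of -6.63 ± 0.29 SE (adjusted p = 0.000137 and 1.42e-05). Of the 40 tested members of the list, 34 fell, none rose and 6 did not pass, and adjusted over the list alone 34 fell too. The median difference was -4.39 (camera adjusted p = 1.09e-18, and adjusted p = 0.212 with an estimated correlation). Ms4a1, the gene of CD20, differed between the 3 arrays labelled without IRF4 (9.23, 7.72 and 4.84) and had a difference of -4.20 ± 0.95 SE (adjusted p = 0.0147). Its call was lost without replicate 2 of that group (-3.97, adjusted p = 0.0570), with adjusted p between 0.000774 and 0.0570 over all settings.

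Transcripts for antigen presentation through MHC class II fell with the B cell genes. Ciita, the class II transactivator, fell from 7.31 ± 0.21 to 3.39 ± 0.18 (adjusted p = 5.5e-06), and H2-Aa, a class II chain, from 9.62 ± 0.38 to 3.50 ± 0.37 (adjusted p = 1.17e-05). Cd74, the invariant chain, fell from 11.01 ± 0.24 to 5.95 ± 1.00 (adjusted p = 0.000696). Of 14 tested members 11 fell, none rose and 3 did not pass, with 11 lower when adjusted over the list alone (median -3.92, camera adjusted p = 5.01e-06, and adjusted p = 0.212 with an estimated correlation). Signalling genes of the B cell receptor and Toll-like receptors moved the same way, with 15 of 21 lower, none higher and 6 not passing, and 16 lower adjusted over the list alone. They included the kinase gene Btk (-5.95 ± 0.13 SE) and Prkcb (-5.40 ± 0.44 SE), and the list's median was -2.44, or -1.52 with no filter (camera adjusted p = 3.22e-08, and adjusted p = 0.212 with an estimated correlation). In the list of B cell progenitor genes, 5 of 9 fell, none rose and 4 did not pass, the same counts as adjusted over the list alone. Il7r, the receptor chain for interleukin 7, was among them (-4.86 ± 0.17 SE). That list's camera adjusted p was 0.00466, and adjusted p = 0.243 with an estimated correlation.

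Over the whole array, 4275 of 11723 tested genes passed the threshold, 1999 higher and 2276 lower on the arrays labelled IRF4. Of these, 1689 differed at least 2-fold (876 higher and 813 lower) and 233 at least 16-fold (89 higher and 144 lower). In 373 of the 2-fold calls, every array of the dimmer group lay under its own array median, so the size of those differences depends on the signal floor. The groups did not overlap for 46.0% of tested genes, where chance gives 5.71%. The 8 genes with the highest positive differences were Klra17 (7.85 ± 0.12 SE), Gpnmb (7.73 ± 0.34 SE), Cd34 (7.04 ± 0.28 SE), Tmem176b (7.02 ± 0.22 SE), Tnfrsf17, Tent5c, Prdm1 and Robo1. Klra17 belongs to the Ly49 receptor family, whose members resemble each other in sequence. Cd34 encodes a surface protein of haematopoietic progenitors and endothelium, and Tent5c a poly(A) polymerase that is mutated in human myeloma. The 8 genes with the largest falls were Cd72 (-7.42 ± 0.28 SE), Cd53 (-6.99 ± 0.23 SE), Ebf1, Ly86, Ifi203, Cd79b, H2-Ab1 and Bcat1. Limma's treat test against a log2 difference of 0.58 kept 1215 genes, 626 higher and 589 lower.

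Genes of the endoplasmic reticulum and secretory pathway rose together. Of 56 tested members, 41 rose, 2 fell and 13 did not pass, and adjusted over the list alone 43 rose and 2 fell. Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, rose by 4.35 ± 0.30 SE (adjusted p = 0.000117), and the coat protein gene Sec24d by 3.13 ± 0.48 SE (adjusted p = 0.00319). Ern1, which encodes the stress sensor IRE1, rose by 2.69 ± 0.21 SE (adjusted p = 0.000198). The median difference was 0.63 (camera adjusted p = 3.25e-12, and adjusted p = 0.341 with an estimated correlation). Among autophagy and lysosome genes 9 of 26 rose, 1 fell and 16 did not pass, with 11 higher and 1 lower adjusted over the list alone. Wipi1, an autophagosome protein gene, rose by 4.17 ± 0.21 SE, and Npc1, a lysosomal cholesterol transporter gene, by 2.37 ± 0.13 SE (camera adjusted p = 0.00175, and adjusted p = 0.341 with an estimated correlation). Of 31 respiratory chain genes 11 rose, none fell and 20 did not pass, the same counts as adjusted over the list alone. Ndufa1 rose by 1.21 ± 0.18 SE and Cox4i1 by 0.54 ± 0.06 SE, and the median of the list was 0.12, or 0.19 without replicate 1 labelled without IRF4 (camera adjusted p = 0.00375, and adjusted p = 0.434 with an estimated correlation).

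Of the cell cycle genes, more fell than rose. Mki67, a marker of cycling cells, lay at 10.28 ± 0.04 and 10.23 ± 0.12 (adjusted p = 0.624). Of 33 proliferation genes, 14 fell, 18 did not pass and 1 rose, the same counts as adjusted over the list alone, with a median of -0.26. The gene that rose was Ccne1, the gene of cyclin E1 (2.74 ± 0.22 SE, adjusted p = 0.000236), and E2f2 had the largest fall (-1.52 ± 0.14 SE, adjusted p = 0.000459). The camera call for lower proliferation genes (adjusted p = 0.00793) was lost at adjusted p = 0.689 with an estimated correlation, and at adjusted p = 0.0739 with fry. Among cyclins, their kinases and their inhibitors 3 of 16 rose, 5 fell and 8 did not pass, with 3 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.399). Cdk6, a kinase of the D-type cyclins, had a difference of -5.54 ± 0.22 SE (adjusted p = 1.08e-05), and Cdkn2b, an inhibitor of that kinase, one of 1.98 ± 0.33 SE (adjusted p = 0.00441). Ccnd2, the gene of cyclin D2, was uneven, at 8.59, 11.11, 11.10 and 6.41 on the arrays labelled IRF4 against 4.77, 6.43 and 4.52. Its call (4.06 ± 1.24 SE, adjusted p = 0.0430) was lost with no filter (4.06, adjusted p = 0.0731). It was also lost when any array other than replicate 4 labelled IRF4 was left out (adjusted p 0.0675 to 0.127), against adjusted p = 0.00804 without that array, the lowest of all settings.

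Adhesion and homing receptors were mostly lower, with 12 of 22 lower, 3 higher and 7 not passing, the same counts as adjusted over the list alone (median -1.51). The integrin chain gene Itgb2 fell by 4.15 ± 0.14 SE and S1pr1, a receptor that guides exit from lymphoid tissue, by 4.71 ± 0.21 SE. The list's camera adjusted p was 0.0367, and adjusted p = 0.243 with an estimated correlation. That call was also lost without replicate 2 labelled without IRF4 (-1.49, adjusted p = 0.0539) or without replicate 4 labelled IRF4 (-1.41, adjusted p = 0.116). It was lost too with the filter at the 60th percentile (adjusted p = 0.108), with array weights (0.0568) and over members in no other list (0.371), over a range of 0.0187 to 0.371 for all settings of camera. With no filter its median was -0.08.

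No camera call was made for the lists described next. Of 25 interferon-stimulated genes 11 fell and 2 rose, with 13 lower and 2 higher adjusted over the list alone (adjusted p = 0.155). Zbp1, a nucleic acid sensor gene, rose by 4.22 ± 0.34 SE and Trim30a fell by 4.18 ± 0.44 SE. The list passed without replicate 3 labelled without IRF4 (-0.43, adjusted p = 0.0481), with no filter (0.0370) and over members in no other list (0.0484), its median was 0.14 with the filter at the 60th percentile, and adjusted p ran from 0.0370 to 0.689 over all settings of camera. Of 43 genes listed as MYC targets or for ribosome biogenesis 13 fell and 1, the telomerase gene Tert, rose 2.83-fold, the same counts as adjusted over the list alone (adjusted p = 0.0718). That list passed without replicate 1 labelled without IRF4 (adjusted p = 0.0287), without replicate 3 labelled IRF4 (0.0280), with no filter (0.0164) and with trend and robust settings (0.0427), over a range of 0.0164 to 0.689 for all settings of camera. Among p53 targets 6 of 20 rose and 4 fell in both adjustments, that is over all genes and adjusted over the list alone (adjusted p = 0.220), with the death receptor gene Tnfrsf10b at 4.08 ± 0.24 SE and Plk2 at -5.02 ± 0.54 SE. The BCL2 family and caspases had 3 of 18 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.809), with Bok, a BCL2 relative, at 1.65 ± 0.17 SE. Among germinal centre genes 2 of 16 rose and 3 fell, unchanged when adjusted over the list alone (adjusted p = 0.809), and Bcl6, a repressor of Prdm1, fell from 4.35 ± 0.33 to 3.07 ± 0.19. NF-kappaB targets had 2 of 22 higher and 6 lower in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.676), with the subunit gene Rel at -4.52 ± 0.34 SE. Among genes of B-1 and marginal zone cells 3 of 12 fell and none rose, as when adjusted over the list alone (adjusted p = 0.329), with Plac8 at -5.74 ± 0.23 SE and Dtx1 at -2.38 ± 0.17 SE.

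Class I presentation genes had 3 of 12 lower and none higher, likewise when adjusted over the list alone (adjusted p = 0.390), with the class I transactivator gene Nlrc5 at -1.92 ± 0.31 SE. Of 24 ATF4 and amino acid genes 3 rose and 2 fell, or 2 and 1 adjusted over the list alone (adjusted p = 0.892). Among Polycomb and Hox genes 1 of 14 rose and 5 fell, or 2 and 5 adjusted over the list alone (adjusted p = 0.442), with the Polycomb genes Pcgf2 at 1.60 ± 0.15 SE and Suz12 at -0.58 ± 0.07 SE. Genes listed as associated with myeloma went both ways, with 6 of 27 higher and 11 lower, also adjusted over the list alone (adjusted p = 0.471). Glycolysis had 2 of 18 genes higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.809), and Pdk1, a kinase that restrains pyruvate use, fell by 4.91 ± 0.22 SE. Of 20 sterol synthesis genes 8 fell and 3 rose, or 9 and 3 adjusted over the list alone (adjusted p = 0.220), with the enzyme genes Cyp51 at -1.15 ± 0.21 SE and Tm7sf2 at 1.49 ± 0.30 SE. Of 23 ribosomal protein genes 2 fell and none rose, with 0 calls adjusted over the list alone (median -0.05, adjusted p = 0.239). The median, mean and camera direction differed in sign, among lists tested with camera, for those of ATF4 genes, BCL2 family genes, germinal centre genes and myeloma genes. With camera's estimated correlation 0 lists passed, with 4 at an unadjusted p under 0.05, while the directional fry test passed 19 of the 28 lists, among them 9 of the 10 that camera called.

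**Figure D2:**
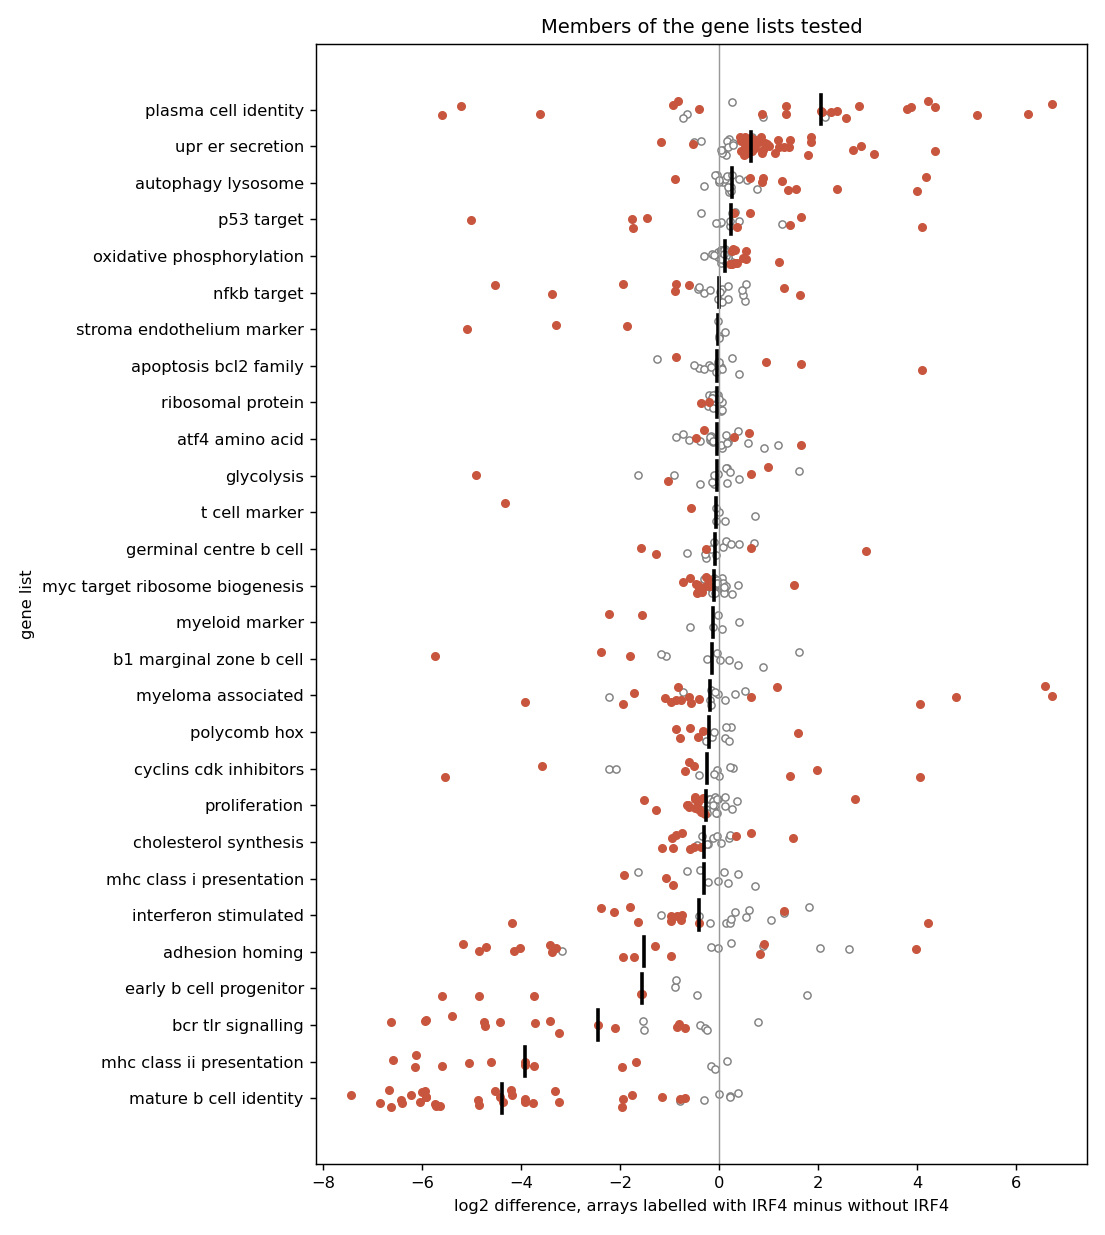
Log2 difference of each tested member of the 28 gene lists with at least 5 tested members, arrays labelled IRF4 minus those labelled without IRF4. Filled points passed the threshold over all genes, open points did not, black bars mark the list medians (from -4.39 for mature B cell genes to 2.05 for plasma cell genes), and the vertical scatter within a list has no meaning.

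Few markers in the fixed lists of other cell types differed upward. Cd34, a gene of haematopoietic progenitors and endothelium, was not in these lists and rose by 7.04 ± 0.28 SE. Among 29 tested markers of T cells, natural killer cells, myeloid cells, dendritic cells, erythroid cells and megakaryocytes, and stroma and endothelium, 9 fell and 0 rose under limma, with 3 higher at an unadjusted p under 0.05. The falls included Cd2 (-4.33 ± 0.27 SE), the integrin gene Itgam (-2.22 ± 0.29 SE) and Vim, the gene of vimentin (-5.10 ± 0.55 SE). By list, 2 of 7 T cell markers fell (camera adjusted p = 0.471), 2 of 7 myeloid markers (0.399) and 3 of 7 stroma and endothelium markers (0.188), counts that stood when adjusted over the list alone. Of 3 natural killer cell markers 1 fell, as did 1 dendritic cell marker of 4 and 0 erythroid or megakaryocyte markers of 2, again as adjusted over the list alone; those lists were too short for the camera test. The T-bet gene Tbx21, chosen after its value was seen, was the only marker with a group difference of log2 1 or more upward (2.58, adjusted p = 0.0979), and lay at 3.95 ± 0.16 and 6.53 ± 2.02. Replicate 1 labelled IRF4 was at 9.54 against 5.39 to 5.77 for the other 3 of its group, and without it Tbx21 passed as higher (1.57, adjusted p = 0.0012, over a range of 0.0012 to 0.206 for all settings). Counted after the data were seen, at most 2 markers of these lineages passed as higher in any of 15 other settings, which leave out treat and single probe sets, and 4 to 10 passed as lower.

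Immunoglobulin genes differed widely between arrays of a group. Among the 3 tested genes annotated as constant regions none passed, also adjusted over the list alone. The tested probe set of Ighm, the heavy chain of IgM, reached 8.84 on replicate 3 labelled IRF4 against 4.40 to 4.50 on the other 3 of its group. That of Ighg3 (10403015) reached 10.13 there against 4.06 to 4.22. Another Ighm probe set (10402991) reached 7.10 there, while another Ighg3 probe set (10403046) stayed dim at 3.07. The signal of probe set 10403015 may therefore not show the constant region. A kappa variable segment (probe set 10538921) was 114-fold above the median of the other arrays on that same array, at 11.67. Igkv10-96 was 50.7-fold above it on replicate 1 labelled without IRF4 (11.57) and 10.5-fold above it on replicate 3 labelled IRF4 (9.30). The probe set annotated as Igkc, the kappa constant region, lay between 6.52 and 9.04 on the arrays labelled without IRF4. It lay between 6.53 and 10.70 on those labelled IRF4 (adjusted p = 0.476). Its lowest value in that group was on replicate 3, where probe set 10538921 was bright. A probe set shared by 3 kappa variable segments (10545187) went the same way, at 10.29, 9.72, 6.23 and 6.78 on replicates 1 to 4 labelled IRF4. The Igkc probe set may therefore read variable segments, and its values may not give the level of the constant region. Probe sets with 1 symbol stood at least 8-fold above the median of the other arrays 6 times, 1 of them on replicate 1 labelled without IRF4 and 5 on replicate 3 labelled IRF4. Variable segments resemble each other, and a probe set can take signal from more than the segment or constant region it names.

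**Figure D3:**
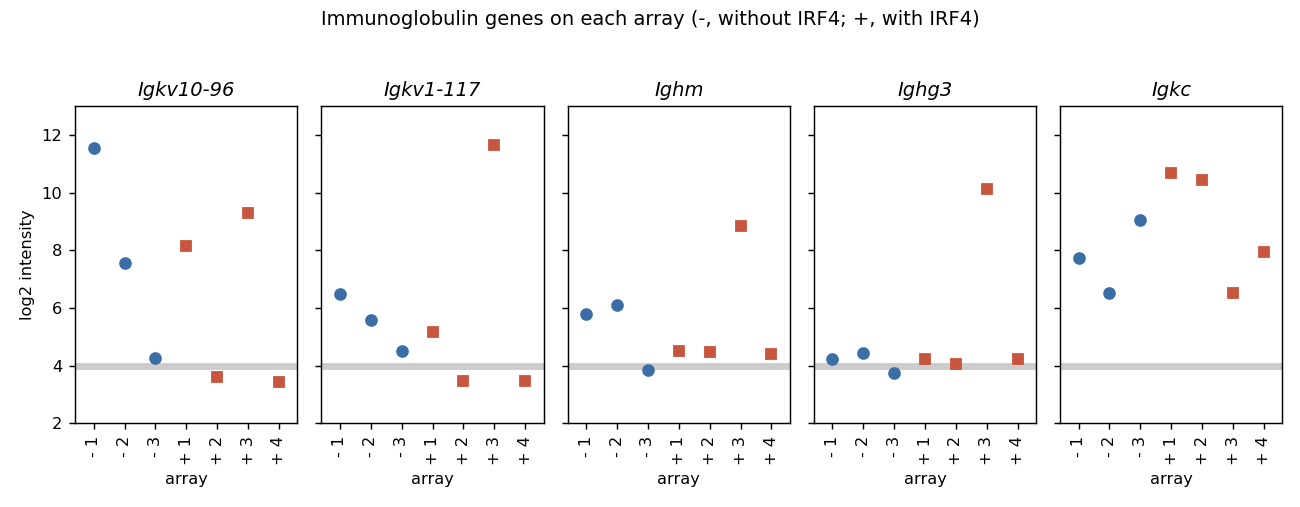
Log2 intensity of 2 kappa variable segments and 3 genes annotated as immunoglobulin constant regions on each of the 7 arrays (circles, labelled without IRF4; squares, labelled IRF4), with a grey band over the range of the array medians. The segment of probe set 10538921, Ighm and Ighg3 reached 11.67, 8.84 and 10.13 on replicate 3 labelled IRF4.

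Replicate arrays resembled each other more than arrays of the other group. Over the tested genes, Pearson's r across genes was 0.981 to 0.987 between arrays labelled without IRF4 and 0.957 to 0.982 between arrays labelled IRF4. Between the groups it was 0.839 to 0.876. Genes are not independent replicates, so these values describe similarity and carry no test. The first principal component held 77.7% of the variance and separated the groups. The second held 8.34%, with replicate 4 labelled IRF4 at -44.2 against 10.8 to 22.2 for the other 3 of its group. The median SD of a gene was 0.114 on the arrays labelled without IRF4 and 0.164 on those labelled IRF4. Without replicate 4 labelled IRF4, 4206 genes passed the threshold.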

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

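The tests weighed here for Irf4, for the B cell genes and for the immunoglobulin segments were chosen after the results were seen; the counts over other splits of the arrays were planned. Of the 35 ways to split the 7 arrays into 3 and 4, 1 gave as many as 4275 genes, the real one, and the highest of the others gave 14. This argues against chance but cannot exclude it, because 1 in 35 is the lowest share this check can give. The other splits mix the groups and so widen the spread within them, which makes low counts likely in advance. For 2-fold calls the real count was 1689 and the highest other 12, again with 1 of 35. For the number of gene lists called by camera the check does not argue against chance, because 8 of the 35 splits gave at least the real 10 and the highest other gave 11.

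Irf4 was lower on the arrays labelled IRF4, against the label. An exchange of whole sample records between the groups is argued against by Prdm1, which lay 6.24 higher on the arrays whose records describe plasma cells. That mouse probe sets do not see the transduced cDNAs stays open, since Myc, Bmi1 and Bcl2l1, transduced in all 7 cultures, reached at most 5.69, with Bcl2l1 above the median of every array. This may account for the missing signal of the virus, and it leaves the fall of the cells' own Irf4 unexplained. Silencing of the endogenous gene by transduced IRF4, a wrong statement of which pool held IRF4, and loss of the virus during culture stay open and were not tested.

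B cell genes fell by a median of 4.39 on the log2 scale. A shift of all genes from the normalization is argued against by ribosomal protein genes, whose median difference was -0.0467. The arrays had been brought to one scale before deposit, so a small value was likely in advance. It does not bear on artefacts limited to some probe sets or intensities. Takeover by the 6 other lineages with marker lists is argued against by their tested markers, of which 0 rose. At most 2 were higher in any of 15 other settings, treat and single probe sets not among them. The 9 markers that fell do not bear on takeover, and some were bright on the arrays labelled without IRF4, such as Vim at 11.30. The lists did not hold Klra17, Gpnmb, Cd34 or Tmem176b, which were among the 8 highest positive differences. The argument therefore covers the listed markers alone. Whether cells of the B lineage remained cannot be told from the brightest of 37 immunoglobulin probe sets. It lay at least 2.34 log2 units above the 75th percentile on each of the 4 arrays labelled IRF4, but so did the brightest of 93.4% of 1000 random sets of that size. Immunoglobulin probe sets at least 8-fold above the median of the other arrays numbered 2, 2, 9 and 0 on replicates 1 to 4 labelled IRF4. They reached 11.55, 12.06 and 11.99 on the first 3. These counts and values were not set against random sets. On replicates 1 and 2 they rest on probe sets with several symbols alone, so no conclusion is drawn for them. On replicate 3, 5 had 1 symbol, the highest 114-fold above that median. This argues against a loss of all B lineage cells in the culture of replicate 3. For replicates 1, 2 and 4 the immunoglobulin probe sets leave the question open, and the share of such cells was not tested. Plasma cell genes, of which 16 rose and 6 fell between the groups, were not weighed for it. On replicate 4, Tnfrsf17 lay at 9.81 and Prdm1 at 10.58, but Mzb1 at 4.06 and Jchain at 3.11. Cells of a lineage outside those lists, culture time, which may differ between the groups, and the addition of IRF4 stay open.

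Several immunoglobulin probe sets were bright on 1 or a few arrays of a group, while a probe set shared by 3 lambda genes followed the groups, at 10.23 to 10.57 on the arrays labelled without IRF4 and 5.48 to 7.40 on those labelled IRF4. Of the 25 kept immunoglobulin probe sets, 68.0% had an SD within the groups above the 95th percentile of all kept probe sets, so they varied more than most. This measures the same spread as the pattern it was chosen for. It is therefore no separate argument against ordinary spread between replicates. A candidate explanation is outgrowth of a few clones with their own rearrangements, which was not tested, and probes shared between similar segments stay open. The design names no group that bears on this, so no biological explanation was tested.

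A closer look is due where 1 of the 4 arrays labelled IRF4 lay far from the other 3. This was so for 13 of 142 genes examined. Chance gives about 1 in 20 for genes chosen without regard to their values, which does not hold for all of these, so the share was not set against it. On replicate 3, the tested probe sets of Ighm and Ighg3 lay at 8.84 and 10.13, both above their group. Prkcb lay there at 5.26 against 3.53 to 3.78, and Laptm5, a lysosomal protein gene, at 7.04 against 4.30 to 4.76. Igf1 lay at 5.24 there against 8.65 to 8.96, and Prdm1 at 10.15 against 10.58 to 10.66. On replicate 4, Lmo2 lay at 7.88 against 9.35 to 9.65, Bmi1 at 4.41 against 3.42 to 3.54, and Map1lc3a at 6.45 against 5.52 to 5.65. On replicate 1, Icam1 lay at 5.52 against 3.72 to 3.85, Btk at 3.42 against 2.98 to 3.04, Itga2b at 3.38 against 3.87 on each of the others, and Tbx21 at 9.54 against 5.39 to 5.77. The values of Btk and Itga2b lay under the median of every array labelled IRF4, so their gaps may be spread near the signal floor.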

How the results depend on the processing

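The immunoglobulin count with shared probe sets and the spread without replicate 4 labelled IRF4 were chosen after the data were seen. Irf4 stayed lower past the threshold in all 15 settings (-4.41 to -4.11, adjusted p 6.61e-06 to 0.0026). Counts of called genes stayed within 1.5 times of 4275 except with treat, which tests against 0.58 and gave 1215 genes, 626 higher and 589 lower. With 1 array left out the count ran from 3129 to 4206, and the 2-fold count from 1476 to 1687. With an estimated correlation the camera calls were lost for mature B cell genes (median -4.39), class II presentation (-3.92), receptor signalling (-2.44), plasma cell genes (2.05) and the secretory pathway (0.63); adjusted p over all settings ran up to 0.212 for the first 4 and 0.341 for the last, and with arrays left out it stayed at or under 0.0011 for all 5. Immunoglobulin probe sets above the other arrays numbered 13 at 4-fold, 4 at 16-fold and 21 with probe sets of several immunoglobulin symbols added, against 6. The lowest correlation within a group, 0.957, was 0.697 over the 1000 genes of highest variance, which is set by that choice of genes, and 0.968 without replicate 4 labelled IRF4.

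The replicate numbers do not pair the arrays, since each culture had its own spleen and virus preparation, and deviations of same-numbered arrays correlated at 0.0531, -0.0686 and -0.0666; only number 1 correlated best with itself. With the replicate block 3156 genes passed, 2938 of them among the 4275, with 49.3% higher, on fewer residual degrees of freedom. Replicate 4 labelled IRF4 has no same-numbered array in the other group, so under the block it adds nothing to the differences. Among results named in the text the block ended the calls of Ms4a1 (-4.27, adjusted p = 0.0560, over a range of 0.000774 to 0.0570) and of the adhesion list (-1.41, adjusted p = 0.152, over a range of 0.0187 to 0.371 with camera). Leaving out replicate 4 labelled IRF4 alone also ended the adhesion call, at the same median (camera adjusted p = 0.116). Across the settings that leave out no array, 26 values of single genes lost their call and 1 gained one. These settings include the block, although replicate 4 labelled IRF4 adds nothing to its differences. With arrays left out 75 values lost their call and 1 gained one. No value in either group of settings changed sign with a call. What caused those losses was not tested. Signal over background limits the sizes of differences where an array is dim.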

Other observations

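Immunoglobulin probe sets with several genes were looked at after the data were seen, and the leukocyte list was tested after the first 3 genes named here had been seen. Ptprc, the gene of the leukocyte surface protein CD45, fell from 8.95 ± 0.31 to 3.44 ± 0.13 on the arrays labelled IRF4 (log2, adjusted p = 2.77e-06). Spi1, the gene of the transcription factor PU.1, had a difference of -6.01 ± 0.11 SE, and Pou2af1, a coactivator gene of B cells and plasma cells, one of -6.29 ± 0.14 SE. After these were seen, a list of 35 genes used by leukocytes of all lineages was written down before its own values were looked at, with the hypothesis that most would be lower. Of 32 tested members 22 fell (68.8%), 1 rose and 9 did not pass, and 25 fell and 1 rose adjusted over the list alone (median -2.65, camera adjusted p = 6.93e-09, and adjusted p = 0.176 with an estimated correlation). Laptm5 was among those that fell (-5.46 ± 0.66 SE), while Lcp1, an actin-bundling protein gene, lay at 10.77 and 10.67. A broader change than loss of B cell identity is a hypothesis from these data. The list cannot tell it from that loss, because genes used by leukocytes of all lineages are also genes of B cells. Spi1 was itself a member of the mature B cell list.

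Probe sets shared by several immunoglobulin genes varied between arrays, and the brightest probe set was the same on replicate 3 labelled without IRF4 and replicate 4 labelled IRF4. The brightest immunoglobulin probe set of an array lay at 11.57, 12.54 and 10.46 on replicates 1, 2 and 3 labelled without IRF4, and at 11.55, 12.06, 11.99 and 9.66 on replicates 1 to 4 labelled IRF4. The probe set at 12.54 is shared by a pair of kappa variable segments and was 55.9-fold above the median of the other arrays.

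Xist, expressed from the inactive X chromosome of female cells, lay at 11.24 ± 0.06 on the arrays labelled without IRF4 and 11.32 ± 0.09 on those labelled IRF4 (adjusted p = 0.433).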
